A study of Callithrix jacchus with 39 samples.

How the data were processed

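RNA sequencing of common marmoset ESCs and early embryos was analysed in 39 libraries, 18 from ESCs and 21 from embryos. RNA extraction used the RNeasy Mini kit, and stranded libraries were prepared from poly(A)+ transcripts with TruSeq Stranded mRNA LT reagents, per the labels' protocols. Reads were trimmed with Trim Galore 0.4.0, aligned with STAR 2.5.3a and counted per gene with featureCounts 1.5.2, per the submitters' processing notes. The genome build and the annotation are not given in the sources used here. The deposited values were raw counts per gene, with 30811 Ensembl gene IDs and 2 columns per library. Another 6 columns, from 3 libraries that belong to no sample of this series, were not used in any step.

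The 78 columns used were summed to 39 libraries, since the 2 columns of a library differed by a chi-square per gene of 1.91 to 2 over genes with at least 50 counts, far below the lowest value between 2 libraries of a group (28.1). Among counts of 1 to 49, 65% were even, against 50.8% of counts of 500 or more, so mates of a read pair appeared to be counted separately. Counting intervals and floors were therefore read as optimistic, and all tests were repeated with halved counts. Groups came from the sample titles alone. Gene symbols were joined by gene ID to the reference gene table and covered 12660 IDs (41.1%), which held 73.8% to 78.7% of the counts of a library. A total of 7 symbols belonged to 2 IDs each. Genes without a symbol were tested but could not be named or placed in a list.

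ESC and embryo libraries were fitted separately with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM normalization and robust dispersion estimates, which left 17957 genes for ESCs and 16929 for embryos. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were naive against primed cells in DSY-c2 and in N40, the difference and the mean of these effects, primed Tg cells against DSY127 and No.40, DSY127 against No.40, each of 6 steps between successive embryo stages, epiblast against the mean of 5 blastocyst ICM stages, and an F test over 7 stages. CPM used TMM-scaled library sizes, the SE of a log2 fold change was its size over the square root of F, and log2 CPM used a prior count of 2. A fold against a group with no count was given as a lower bound against a floor of 3 counts over the group.

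With 3 libraries per group, total counts of 38.8 to 78.7 M (mega, 1e6) limited the tests less than the spread between libraries. Tested on simulated data made from these libraries, with 100 genes changed at each fold, a 2-fold change was recovered for 40% of genes in DSY-c2, 45% in N40, 48% in Tg against DSY127, 1% from blastocyst to expanded ICM and 4% in epiblast against ICM. A 4-fold change was recovered for 62%, 79%, 75%, 16% and 30%. False calls numbered 5 of 107, 8 of 132, 3 of 126, 0 of 17 and 2 of 36 calls. Each simulation changed 200 of 16604 to 17596 genes. The real DSY-c2, N40 and epiblast against ICM tests called 58.8%, 61% and 44.8% of genes, so their recovery and false calls may differ.

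The 29 gene lists were written before the data were examined, as were the groups, comparisons, main tests and the rule for naming genes. The lists covered naive, primed and shared pluripotency, reprogramming factors, trophectoderm, primitive endoderm, amnion, mesoderm, neural, primordial germ cell, DNA methylation, FGF-ERK, LIF-STAT3, WNT, NODAL, BMP, glycolysis, oxidative phosphorylation, cholesterol synthesis, maternal oocyte, zygotic genome activation, fibroblast, maternal tissue, p53, integrated stress response, cell cycle, epithelial, mesenchymal and mitochondrial genome genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a comparison. Lists with fewer than 3 tested genes had no set test.

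In the 2 naive against primed comparisons and in epiblast against ICM, the 8 largest rises and 8 largest falls were named, among called genes with a symbol, a mean of at least 10 CPM in the higher group and no overlap between libraries. In the other comparisons it was 3 each way, and overlap between libraries was not checked for the difference and the mean of the naive effects. All reprogramming factors, up to 4 called members per list and any member of the 3 pluripotency lists were also open to naming. Not every gene under this rule is printed, and 1 result is not reported.

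Naive effects were compared with the ICM minus epiblast effect by correlation over genes tested in both fits. The similarity of an ESC library to the embryo was the Pearson's r of log2 CPM with a stage mean over the genes called in the F test, and naive and primed libraries were compared by exact permutation. A total of 3 correlations over genes were computed between comparisons.

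The alternatives were the size factors of DESeq2, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 as the test, fits of only the groups compared, a fold threshold of 2, a block for the replicate number, each library left out in turn, camera with an estimated correlation, fry, concordance over genes above the median level or against hatched ICM only, and similarity with all expressed genes, Spearman's correlation, a prior count of 0.5 or hatched ICM only. Halved counts, the column suffix as a covariate, similarity with a library left out or without markers of other cell types, and concordance over genes of at least 1 CPM in a primed group were added after the data had been seen. Leaving out mitochondrial genome genes was not run, because no symbol of that list was matched.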

Results

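The data were gene counts from poly(A)+ RNA sequencing of the common marmoset, Callithrix jacchus. They covered 39 libraries in 13 groups of 3. Embryonic stem cells (ESCs) gave 18 libraries in 6 groups, and early embryos gave 21 libraries in 7 stages. The ESC groups were primed cells titled DSY127 and No.40, primed and naive cells titled DSY-c2, and primed and naive cells titled N40. The titles of the DSY-c2 and N40 primed libraries carry Tg, those of the DSY-c2 naive libraries TgON and those of the N40 naive libraries TgOFF. The labels do not define Tg, so TgON and TgOFF were not separated from the cell line. The embryo groups were the morula, the inner cell mass (ICM) of early, blastocyst, expanded, hatching and hatched blastocysts, and the postimplantation epiblast. The labels do not say whether libraries of a group came from separate cultures or embryos, so p-values measured the spread between these libraries, which may be technical.

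Total counts ranged from 38.8 to 78.7 M (mega, 1e6) counts per ESC library and from 45.3 to 59 M counts per embryo library. By group, the totals in M counts were 45.9 to 54.6 for DSY127, 38.8 to 56.7 for No.40, 63.4 to 64 for DSY-c2 primed, 62.5 to 72.1 for DSY-c2 naive, 75 to 78.7 for N40 primed and 72.3 to 75.3 for N40 naive. In the embryo they were 52.4 to 59 for morula, 45.3 to 51.8 for early, 49.5 to 55.5 for blastocyst, 52.7 to 53.3 for expanded, 48.7 to 54.3 for hatching and 52.1 to 53 for hatched ICM, and 51.1 to 52.9 for epiblast. Between 15613 and 16722 genes had at least 10 counts in an ESC library, and between 11604 and 15076 did in an embryo library. Libraries of an ESC group correlated across genes at r of 0.959 to 0.994, and the epiblast libraries at 0.952 to 0.955. Morula libraries correlated at 0.865 to 0.909 and ICM libraries at 0.75 to 0.865, so the spread between libraries was widest in the ICM.

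Conversion of primed to naive-like ESCs, the subject of the series, was first examined in DSY-c2. Levels are CPM (counts per 1e6 counts) as mean ± SD over n = 3 libraries, and log2 fold changes carry their standard error (SE). ESRRB (ENSCJAG00000020709), an orphan nuclear receptor of the naive pluripotency network, rose from 0.803 ± 0.458 CPM in primed to 64.9 ± 12.5 CPM in naive cells. KLF17 (ENSCJAG00000003910), a transcription factor of human naive cells, rose from 24.8 ± 3 to 85.9 ± 4.35 CPM. ZIC2 (ENSCJAG00000020988), a transcription factor of primed and postimplantation cells, fell from 246 ± 25.4 to 2.2 ± 1.94 CPM. DNMT3B (ENSCJAG00000015617), a de novo DNA methyltransferase, fell from 2780 ± 710 to 814 ± 103 CPM. POU5F1 (ENSCJAG00000019789), which both pluripotent states need, stood at 1040 ± 174 CPM in primed and 1390 ± 218 CPM in naive cells.

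Of 17957 genes tested with edgeR, 10565 (58.8%) differed between DSY-c2 naive and primed cells, 5311 higher and 5254 lower, and 1947 and 3833 of these at least 2-fold. With the size factors of DESeq2, the share of calls that were higher went from 50.3% to 46.6%. ESRRB gained 6.33 ± 0.36 on the log2 scale (edgeR adjusted p = 1.14e-09). ZIC2 fell by 6.79 ± 0.56 (adjusted p = 1.64e-07) and DNMT3B fell by 1.77 ± 0.18 (adjusted p = 5.14e-07). For each of these 3 genes every naive library lay outside the range of the 3 primed libraries. KLF17 gained 1.79 ± 0.61 (adjusted p = 0.0216), also without overlap, but without primed replicate 2 its change was 1.68 with an adjusted p of 0.0706. Against a fold threshold of 2, 3761 genes were called.

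Among the genes with the largest rises in DSY-c2, BECN2 (ENSCJAG00000021914), a beclin family autophagy gene, went from 0.0549 ± 0.0375 to 165 ± 16.1 CPM. FOXR1, a forkhead factor, went from 0.0852 ± 0.0431 to 36.8 ± 5.61 CPM, and UNC93A, a transporter-like membrane protein, from 0.721 ± 0.286 to 142 ± 26.6 CPM. SCN9A, a sodium channel, went from 0.706 ± 0.161 to 114 ± 18.1 CPM. SLC3A1, LRRC31, OTC and CDH10 completed the 8 largest rises, at naive levels of 12 to 28.4 CPM. Among the largest falls, KDR (ENSCJAG00000018352), the VEGF receptor, went from 57.9 ± 17.9 to 0.154 ± 0.081 CPM. CER1, a secreted NODAL inhibitor, went from 762 ± 1120 to 0.121 ± 0.0993 CPM, with a wide spread because primed replicate 4 alone held 2060 CPM. SPOCK3, a matrix proteoglycan, was 1010-fold lower, with a counting interval of 279 to 8320 from 2 counts in the naive libraries. OPTC, another matrix proteoglycan, fell from 11.8 ± 2.61 CPM to no count and was at least 731-fold lower, against a floor of 3 counts over the group. PCDH20 and SEZ6L were 2250-fold (623 to 18600) and 2170-fold (600 to 17900) lower, and SPHKAP and DKK4 were also among the 8 largest falls. These intervals and floors cover counting error only, at a nominal 95% confidence. They are optimistic, since mates of a read pair appeared to be counted separately. The call for DKK4 ended when any single naive library was left out, at adjusted p of 0.0538 to 0.0602.

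**Figure D1:**
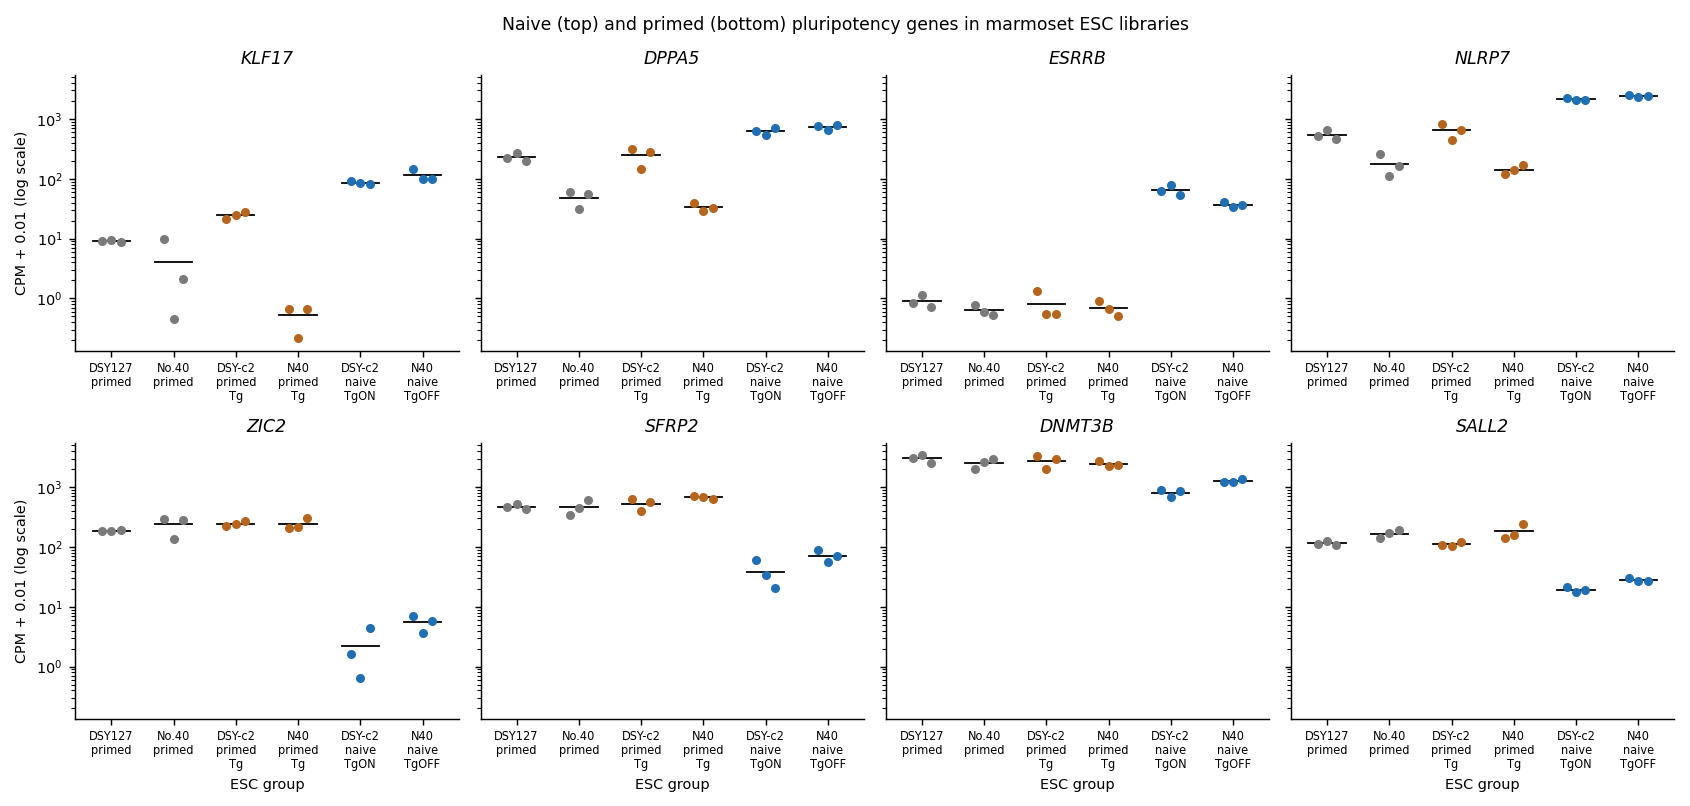
Level of 8 genes in the 18 ESC libraries, as CPM plus 0.01 on a log axis, by group; each point is 1 library and each line a group mean over 3 libraries. The top row shows KLF17, DPPA5, ESRRB and NLRP7 from the naive list, with ESRRB at 64.9 CPM in DSY-c2 naive and 36.7 CPM in N40 naive cells, and the bottom row ZIC2, SFRP2, DNMT3B and SALL2 from the primed list, with ZIC2 at 2.2 and 5.46 CPM.

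The naive pluripotency list was higher in DSY-c2 naive cells. Of its 14 tested genes 12 rose, 0 fell and 2 were not called, and the counts were 12 and 0 adjusted over the list alone (median log2 1.65; camera adjusted p = 0.000359, and 0.162 with an estimated correlation). ARGFX, a homeobox gene of the early embryo, rose by 4.25 ± 0.54 and the germline gene DPPA5 by 1.32 ± 0.26, from 250 ± 89.4 to 622 ± 77 CPM. NANOG held 429 ± 83.3 and 399 ± 67.8 CPM and was not called (log2 -0.11, adjusted p = 0.535). The primed list was lower, with 0 of 12 genes rising and 9 falling (0 and 9 adjusted over the list alone; median -2.14; camera adjusted p = 0.000359, and 0.0359 with an estimated correlation). SFRP2, a WNT pathway modulator, fell from 532 ± 117 to 38.2 ± 20.4 CPM and SALL2, a zinc finger factor, from 110 ± 8.69 to 19.3 ± 2.23 CPM. The neural list had 0 of 7 genes rising and 6 falling (0 and 6 adjusted over the list alone), with a median of -3.26, or -2.8 with 1 gene at its bound (camera adjusted p = 0.00739, and 0.158 with an estimated correlation). All 25 tested genes of the oxidative phosphorylation list rose (25 adjusted over the list alone; median 0.89; camera adjusted p = 6.25e-17, and 0.0577 with an estimated correlation). SDHB, a succinate dehydrogenase subunit, rose from 86.5 ± 9.73 to 382 ± 58.5 CPM.

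Of 27 lists with a set test, these 4 were called with the preset correlation in DSY-c2, and 1 of them, the primed list, with an estimated correlation. The shared pluripotency list had 4 genes higher and 5 lower of 10 (adjusted p = 0.582), with POU5F1 at 0.42 ± 0.14 (adjusted p = 0.0128) and SOX2 at -0.48 ± 0.19 (adjusted p = 0.037). The POU5F1 call ended without primed replicate 2 (0.36, adjusted p = 0.0727), primed replicate 4 (0.31, 0.0964) or naive replicate 3 (0.27, 0.119). The SOX2 call ended without primed replicate 2 (-0.33, adjusted p = 0.179), primed replicate 5 (-0.45, 0.0964) or naive replicate 1 (-0.51, 0.0672), 2 (-0.48, 0.0825) or 3 (-0.52, 0.0629). In a fit of the 2 groups alone, the adjusted p was 0.0725 for POU5F1 and 0.0512 for SOX2. The reprogramming factor list had 2 higher and 3 lower of 6 (0.345), and MYC fell from 229 ± 31.7 to 72.1 ± 13.3 CPM. The mesoderm list had 1 higher and 7 lower of 9 (median -5.45; adjusted p = 0.262), including TBXT, the primitive streak gene brachyury, which went from 55.9 ± 34.9 to 0.601 ± 0.445 CPM. Primed replicate 4 had a mean mesoderm level of 4.48 (log2 CPM) against 2.3 and 2.23 in replicates 2 and 5, and without it the median of the 7 lower genes went from -6.36 to -4.2 and EOMES was no longer called (-2.72, adjusted p = 0.113). The same library stood apart for mesenchymal (6 against 4.05 and 3.69), primitive endoderm (6.71 against 5.38 and 4.84), NODAL (8.18 against 6.19 and 6.45) and WNT genes (4.02 against 2.79 and 1.95), and it correlated best with DSY127 replicate 3 (0.981, against 0.972 in its own group). The WNT response list had 1 higher and 8 lower of 9 (0.262) and the DNA methylation list 2 higher and 6 lower of 8 (0.262), with the demethylase TET2 rising from 18.3 ± 0.201 to 106 ± 6.48 CPM. The glycolysis list had 5 higher and 2 lower of 16 (0.565): hexokinase 2, HK2, rose from 79.3 ± 39.7 to 486 ± 85 CPM and the neuronal enolase ENO2 fell from 117 ± 37.9 to 11.5 ± 8.28 CPM. The counts of these 6 lists were the same adjusted over the list alone.

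The remaining lists in DSY-c2 were not called by camera, while fry, which tests each list without reference to other genes, called 19 of 27 lists. Counts of genes higher and lower were 4 and 3 of 11 for trophectoderm (adjusted p = 0.957), 3 and 5 of 16 for primitive endoderm (0.582), 3 and 0 of 6 for amnion (0.499) and 5 and 1 of 8 for primordial germ cells (0.184). They were 1 and 2 of 7 for FGF-ERK response (0.931), 5 and 1 of 8 for LIF-STAT3 response (0.184), 2 and 3 of 6 for NODAL response (0.931), 6 and 4 of 15 for cholesterol synthesis (0.612) and 3 and 4 of 10 for maternal oocyte genes (0.931). Zygotic genome activation had 2 and 0 of 4 (0.38), fibroblast genes 2 and 7 of 11 (0.093), maternal tissue 1 and 1 of 5 (0.926) and p53 response 4 and 1 of 5 (0.262). The integrated stress response had 2 and 6 of 9 (0.262), the cell cycle 10 and 5 of 18 (0.262), epithelial genes 3 and 2 of 9 (0.565) and mesenchymal genes 0 and 6 of 8 (0.336). The BMP response list, with 2 tested genes, had 1 and 0 and no set test, and no gene of the mitochondrial genome list was matched. Adjusted over the list alone, these counts were the same except 1 and 1 for FGF-ERK, 2 and 7 for the integrated stress response, 10 and 6 for the cell cycle and 1 and 1 for BMP. Median, mean and test differed in sign for FGF-ERK (-0.74, 0.05, down), NODAL (-0.33, -2.33, up), maternal oocyte (-0.37, -0.61, up), maternal tissue (-0.92, -0.35, up) and epithelial genes (0.04, -0.04, up). The amnion median was 2.87, or 2.33 with 1 gene at its bound.

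In N40 the naive-like cells carried TgOFF in their titles. KLF17 rose from 0.508 ± 0.261 CPM in primed to 115 ± 28.1 CPM in naive cells, and DPPA5 (ENSCJAG00000009945) from 33.7 ± 5.06 to 743 ± 73.9 CPM. NLRP7, a maternal-effect gene that marks the naive state, rose from 143 ± 22.7 to 2440 ± 107 CPM. KLF4, a reprogramming factor, rose from 140 ± 6.17 to 759 ± 114 CPM and NANOG from 535 ± 51.7 to 958 ± 53.7 CPM. ZIC2 fell from 243 ± 53.6 to 5.46 ± 1.66 CPM. POU5F1 held 1580 ± 81.2 and 1480 ± 42.6 CPM and SOX2 164 ± 34.2 and 158 ± 11.5 CPM, and neither was called (adjusted p = 0.533 and 0.815). In a fit of the 2 groups alone POU5F1 was called, at -0.2 with an adjusted p of 0.0332.

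In N40, edgeR called 10952 genes (61%), 5794 higher and 5158 lower in naive cells, and 2689 and 3564 of these at least 2-fold. The share of calls that were higher went from 52.9% to 48.6% with the size factors of DESeq2, so the larger side depends on the scaling. KLF17 gained 7.82 ± 0.83 (adjusted p = 1.81e-06), DPPA5 4.46 ± 0.29 (6.11e-09) and KLF4 2.43 ± 0.2 (3.09e-08). ZIC2 fell by 5.48 ± 0.52 (5.03e-07). Each of these genes was separated between the 3 naive and 3 primed libraries. BECN2 went from no count to 173 ± 26 CPM, at least 13300-fold higher, and ARGFX from no count to 27.2 ± 6.22 CPM, at least 2080-fold higher. TLX1, a homeobox gene, went from no count to 22.7 ± 8.52 CPM, at least 1750-fold higher, and MIOX, an inositol oxygenase, from 0.0636 ± 0.0642 to 173 ± 88.1 CPM. GATA6, an endoderm transcription factor, went from 0.0597 ± 0.0372 to 25.5 ± 13.1 CPM and HNF4A, a hepatic and endoderm factor, from 0.179 ± 0.0641 to 67.8 ± 11.2 CPM. The primitive endoderm list had 4 higher and 4 lower of 16 (camera adjusted p = 0.646). Naive replicate 1 stood apart for its genes, at a mean log2 CPM of 4.28 against 3.45 and 3.33 in replicates 2 and 3. For fibroblast genes it stood at 3.78 against 2.65 and 2.57. The largest falls included PGM5 (230 ± 34.9 to 0.111 ± 0.0331 CPM), a cell adhesion protein, the natriuretic peptide NPPB (38.6 ± 19.4 to 0.0689 ± 0.0846 CPM), the cilium gene DRC1 (106 ± 47.2 to 0.213 ± 0.0628 CPM) and KDR (112 ± 68.5 to 0.405 ± 0.653 CPM). Against a fold threshold of 2, 4266 genes were called.

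6 of 27 lists were called in N40 with the preset correlation, and 0 with an estimated one. In the naive list 11 of 14 genes rose and 1 fell (11 and 1 adjusted over the list alone; median 3.28; camera adjusted p = 5.32e-07, and 0.125 with an estimated correlation). The gene that fell was PRDM14, a germ cell and pluripotency regulator, from 434 ± 113 to 213 ± 18.3 CPM. In the primed list 2 of 12 rose and 8 fell (2 and 8 adjusted over the list alone; median -1.95; camera adjusted p = 0.0294, and 0.125 with an estimated correlation). The 2 that rose were NEFL, a neurofilament, from 4.27 ± 0.956 to 19.1 ± 3.15 CPM, and FGF2 from 1.39 ± 0.526 to 5.37 ± 1.19 CPM. The oxidative phosphorylation list had 23 of 25 genes rising and 0 falling (23 and 0 adjusted over the list alone; median 0.67; camera adjusted p = 1.56e-07, and 0.189 with an estimated correlation), with SDHB rising from 67.4 ± 5.56 to 370 ± 16.5 CPM. The neural list had 0 higher and 3 lower of 7 (camera adjusted p = 0.0414, and 0.189 with an estimated correlation), led by the cell adhesion gene NCAM1 (14.6 ± 0.356 to 0.344 ± 0.14 CPM). The primordial germ cell list had 7 higher and 1 lower of 8 (camera adjusted p = 0.0435, and 0.195 with an estimated correlation), led by PRDM1 (4.16 ± 3.31 to 74 ± 13.8 CPM). The LIF-STAT3 list had 6 higher and 0 lower of 8 (camera adjusted p = 0.0294, and 0.181 with an estimated correlation). These last 3 counts were the same adjusted over the list alone. The mesoderm list had 1 higher and 1 lower of 9 (adjusted p = 0.677).

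The difference between the 2 conversions was tested as the naive effect in DSY-c2 minus that in N40. KLF17 gained less in DSY-c2 by 6.03 ± 0.96 on the log2 scale (log2 -6.03; adjusted p = 0.00125) and started there from 24.8 against 0.508 CPM. The difference was -3.14 for DPPA5 (adjusted p = 0.000108), -1.79 for KLF4 (0.000483) and -0.95 for NANOG (0.0046). edgeR called 2716 genes (15.1%), 1177 with a positive and 1539 with a negative difference. A negative difference can be a smaller rise or a larger fall in DSY-c2. In the naive list 1 of 14 genes had a positive and 8 a negative difference (3 and 9 adjusted over the list alone). The camera adjusted p of this list was 0.00033, and 0.366 with an estimated correlation. Against a fold threshold of 2, 315 genes differed.

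Averaged over the 2 lines, 12514 genes (69.7%) differed, 6545 higher and 5969 lower in naive cells. ESRRB gained 6.03 ± 0.25 (adjusted p = 6.13e-12), higher in 6 of 6 naive libraries. In the naive list 13 of 14 genes rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 3.57e-06, and 0.0972 with an estimated correlation). Oxidative phosphorylation was higher (25 and 0 of 25, 25 and 0 alone; 2.29e-12 and 0.0972), and primed (1 and 10 of 12, 1 and 10 alone; 0.00247 and 0.0642) and neural genes (0 and 5 of 7, 0 and 5 alone; 0.0131 and 0.119) were lower. Against a fold threshold of 2, 4636 genes were called.

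Primed cells whose titles carry Tg were compared with those titled DSY127 and No.40, although the labels do not state that one derives from the other. PRRX1, a mesenchymal homeobox gene, held 34.6 ± 16.7 CPM in DSY127 and 0.343 ± 0.113 CPM in DSY-c2 primed cells. NR2F1, an orphan nuclear receptor, went from 12.6 ± 8.16 CPM to no count, at least 810-fold lower. SNURF, a gene of an imprinted transcript, rose from 169 ± 8.06 to 335 ± 51 CPM. Of the reprogramming factors, MYC (191 ± 10.2 and 229 ± 31.7 CPM), KLF4, POU5F1, SOX2, NANOG and LIN28A were not called. edgeR called 337 genes (1.88%), 28 higher and 309 lower in DSY-c2 primed cells. The fibroblast list had 0 higher and 5 lower of 11 (0 and 6 adjusted over the list alone; camera adjusted p = 4.24e-10, and 0.19 with an estimated correlation). With the suffix as a covariate its members COL1A2 and DCN were no longer called (adjusted p = 0.084 and 0.274), nor were they without DSY127 replicate 1 or 3 or DSY-c2 primed replicate 2, 4 or 5 (0.07 to 0.186 and 0.105 to 0.216), and in a fit of the 2 groups alone their adjusted p was 0.0949 and 0.0974. Amnion genes (0 and 0 of 6, 0 and 3 alone; 0.00281 and 0.588) and mesenchymal genes (0 and 1 of 8, 0 and 1 alone; 0.00563 and 0.588) were also lower. Oxidative phosphorylation (1 and 0 of 25, 1 and 0 alone; 0.000706 and 0.588) and glycolysis (0 and 0 of 16, 0 and 0 alone; 0.00563 and 0.588) were higher. These 5 lists were called with the preset correlation only: 0 were called with an estimated one, and fry called 0 of 27 lists. The count was 149 without DSY127 replicate 1, 146, 186 and 149 without DSY-c2 primed replicate 2, 4 and 5, 179 against a fold threshold of 2 and 547 with DESeq2. The data columns of DSY127 and DSY-c2 primed carry different suffixes, and 100 genes were called with the suffix as a covariate.

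Between No.40 and N40 primed cells, the mesenchymal genes FN1 and VIM went from 5100 ± 5190 to 149 ± 11.1 CPM and from 751 ± 540 to 36.2 ± 1.5 CPM. POSTN, a matrix gene of fibroblasts, went from 102 ± 116 to 0.0263 ± 0.0259 CPM. FOS, an immediate early gene, held 16.6 ± 6.37 CPM in No.40 and 224 ± 204 CPM in N40. SOX2 rose from 90.5 ± 19.1 to 164 ± 34.2 CPM. edgeR called 3937 genes (21.9%), 1490 higher and 2447 lower in N40 primed cells. The fibroblast list had 0 higher and 7 lower of 11 (0 and 9 adjusted over the list alone; camera adjusted p = 3.94e-06, and 0.378 with an estimated correlation) and the mesenchymal list 0 higher and 6 lower of 8 (0 and 7 adjusted over the list alone; camera adjusted p = 0.000117, and 0.426 with an estimated correlation). Primitive endoderm was also lower (0 and 5 of 16, 0 and 6 alone; 0.033 and 0.784). The No.40 libraries differed among themselves, with mean log2 CPM of 6.84, 6.82 and 4.33 for mesenchymal and 6.59, 5.03 and 4.09 for primitive endoderm genes in replicates 1, 2 and 3. Replicate 1 correlated best with DSY127 replicate 1 (0.977) and replicate 3 with N40 primed replicate 1 (0.977). Shared pluripotency (4 and 1 of 10, 6 and 1 alone; 0.00119 and 0.378), reprogramming factors (3 and 0 of 6, 4 and 0 alone; 0.00153 and 0.426), oxidative phosphorylation (6 and 0 of 25, 8 and 0 alone; 7.94e-05 and 0.426), cell cycle (3 and 0 of 18, 3 and 0 alone; 0.0117 and 0.426) and epithelial genes (2 and 0 of 9, 2 and 0 alone; 0.0335 and 0.443) were higher. The count was 2571 without N40 primed replicate 2, 494 against a fold threshold of 2 and 1748 in a fit of the 2 groups alone, where FOS had an adjusted p of 0.0761.

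Between the 2 primed groups without Tg, DPPA5 held 48.4 ± 15.5 CPM in No.40 and 229 ± 35.2 CPM in DSY127, and NLRP7 180 ± 74.7 and 545 ± 93.6 CPM. RBM44 and RBM46, germline RNA-binding proteins, went from 3.53 ± 2.73 to 74 ± 3.72 CPM and from 5.59 ± 6.02 to 98.6 ± 2.7 CPM. TCAF1, a channel-associated factor, went from 36.4 ± 8 to 5.69 ± 1.08 CPM. edgeR called 802 genes (4.47%), 476 higher and 326 lower in DSY127, and the naive list had 3 higher and 0 lower of 14 (7 and 3 adjusted over the list alone; camera adjusted p = 0.00173, and 0.205 with an estimated correlation). Trophectoderm (3 and 0 of 11, 4 and 0 alone; 0.00479 and 0.17), p53 response (1 and 0 of 5, 3 and 0 alone; 0.00479 and 0.205) and primordial germ cell genes (2 and 0 of 8, 4 and 0 alone; 0.00805 and 0.17) were also higher. So were LIF-STAT3 response (0 and 0 of 8, 4 and 0 alone; 0.0205 and 0.17), WNT response (1 and 0 of 9, 2 and 0 alone; 0.0205 and 0.352) and zygotic genome activation (0 and 0 of 4, 0 and 0 alone; 0.0238 and 0.208). The count was 403, 377 and 399 without DSY127 replicate 1, 2 and 3, and 368 and 470 without No.40 replicate 2 and 3. It was 1165 without No.40 replicate 1, which leaves libraries of one column suffix only, 44 against a fold threshold of 2, 430 in a fit of the 2 groups alone, where NLRP7 and RBM46 had adjusted p of 0.0593 and 0.068, and 1532 with DESeq2.

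In the embryo, 6435 of 16929 genes (38%) differed among the 7 stages in an F test. From morula to early blastocyst ICM, COL4A1 (ENSCJAG00000014430), a basement membrane collagen of primitive endoderm, rose from 1.06 ± 1.09 to 109 ± 81.8 CPM. PDGFRA, a primitive endoderm receptor, rose from 11.9 ± 1.63 to 618 ± 346 CPM. KLF17 and NANOG were not called (88 ± 64.3 to 15 ± 12.3 and 351 ± 173 to 868 ± 405 CPM). edgeR called 1042 genes (6.16%), 658 higher and 384 lower, with COL4A1 at 6.69 ± 1 (adjusted p = 0.000877) and PDGFRA at 5.7 ± 0.72 (0.000276), each higher in 3 of 3 libraries. The cholesterol synthesis list had 9 higher and 0 lower of 15 (9 and 0 adjusted over the list alone; camera adjusted p = 2.07e-07, and 0.31 with an estimated correlation), oxidative phosphorylation 6 and 0 of 25 (12 and 0 adjusted over the list alone; camera adjusted p = 3.42e-06, and 0.31 with an estimated correlation) and primitive endoderm 4 and 0 of 16 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0186, and 0.31 with an estimated correlation). Epithelial genes had 3 and 0 of 9 (3 and 0 alone; 0.034 and 0.31). The count was 513 and 581 without morula replicate 1 and 2, 265 against a fold threshold of 2, 213 in a fit of the 2 groups alone and 2946 with DESeq2.

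From early blastocyst to blastocyst ICM, edgeR called 5 genes higher and 0 lower. CARD10, a signalling scaffold, went from 0.058 ± 0.0503 to 13 ± 11 CPM (log2 7.77 ± 1.13, adjusted p = 0.0136, higher in 3 of 3 libraries), and DHRS13 and ISYNA1 were the other named genes. The DHRS13 call ended without early replicate 3 (6.23, adjusted p = 0.0808) or blastocyst replicate 2 (5.5, 0.0503), and the ISYNA1 call without early replicate 2 (2.13, 0.0729), early replicate 3 (2.04, 0.0974) or blastocyst replicate 3 (1.41, 0.0909). Unadjusted, 2255 genes had p below 0.05, and DESeq2 called 1201. The count was 127, 14 and 12 without early replicate 1, 2 and 3, 103 and 10 without blastocyst replicate 1 and 2, and 0 in a fit of the 2 groups alone. The NODAL response list was higher (0 and 0 of 6 over all genes, 4 and 0 adjusted over the list alone; camera adjusted p = 0.00342, and 0.201 with an estimated correlation). FGF-ERK response (0 and 0 of 7, 3 and 0 alone; 0.0234 and 0.201) and primed genes (0 and 0 of 12, 4 and 0 alone; 0.0327 and 0.201) were also higher, and the cell cycle lower (0 and 0 of 18, 0 and 0 alone; 0.0335 and 0.487), the last not called with the size factors of DESeq2 (0.0541).

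In the next 3 steps, blastocyst to expanded, expanded to hatching and hatching to hatched, edgeR called 0 genes. There, 923, 831 and 1134 genes had an unadjusted p below 0.05, and DESeq2 called 356, 278 and 245. In the first of these steps 1 gene was called without blastocyst replicate 1. Between expanded and hatching ICM the primed list was higher (median 2.31; camera adjusted p = 0.00203, and 0.0367 with an estimated correlation) and so was the mesenchymal list (median 1.21, or 1.05 with 1 gene at its bound; 0.00203 and 0.0367), while the cell cycle list was lower (median -0.15; 0.0223 and 0.305). Of their genes, 0 of 12, 0 of 8 and 0 of 18 were called over all genes or adjusted over the list alone. Between hatching and hatched ICM 5 lists were called, with 0 of their genes called over all genes. Cholesterol synthesis (median 0.87; camera adjusted p = 4.38e-07, and 0.223 with an estimated correlation) and primitive endoderm were higher (1.42; 1.48e-06 and 0.0641). So were trophectoderm (2.24; 0.00145 and 0.223) and the integrated stress response (1.35; 0.0315 and 0.56), while oxidative phosphorylation was lower (-0.29; 0.0212 and 0.636). Adjusted over the list alone, 7 primitive endoderm and 2 stress response genes were higher, and 0 genes of the other 3 lists were called. With an estimated correlation 0 of these 5 lists were called. From expanded to hatching and from hatching to hatched ICM, fry called 0 of 27 lists.

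**Figure D2:**
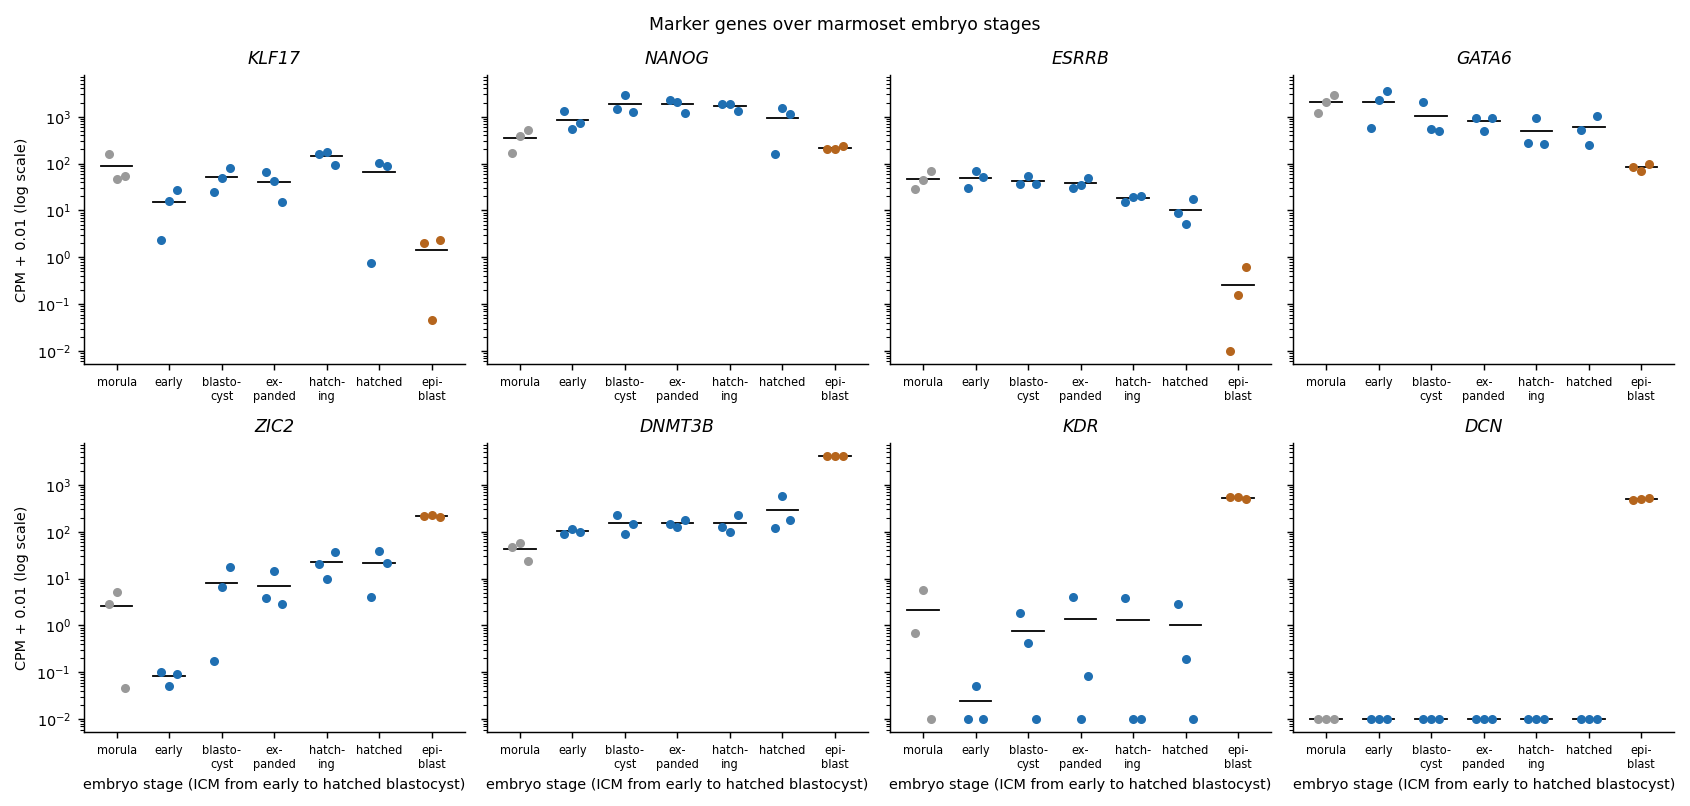
Level of KLF17, NANOG, ESRRB, GATA6, ZIC2, DNMT3B, KDR and DCN in the 21 embryo libraries by stage, as CPM plus 0.01 on a log axis; each point is 1 library and each line a stage mean over 3 libraries. In the postimplantation epiblast DNMT3B stood at 4100 CPM, ZIC2 at 215 CPM and DCN at 500 CPM, while ESRRB stood at 0.25 CPM.

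The step from hatched ICM to the postimplantation epiblast had the largest number of calls among the stage steps. KLF4 fell from 544 ± 209 to 24.2 ± 3.97 CPM, NLRP7 from 1030 ± 356 to 35.4 ± 5.61 CPM and SDHB from 319 ± 55.6 to 29.3 ± 10.4 CPM. DNMT3B rose from 292 ± 248 to 4100 ± 51.1 CPM and SALL2 from 1.41 ± 0.592 to 461 ± 49.3 CPM. edgeR called 3372 genes (19.9%), 1222 higher and 2150 lower in the epiblast. The naive list had 1 higher and 11 lower of 14 (1 and 12 adjusted over the list alone; camera adjusted p = 3.24e-09, and 0.0136 with an estimated correlation). Oxidative phosphorylation (0 and 22 of 25, 0 and 22 alone; 3.27e-17 and 0.019), LIF-STAT3 response (1 and 3 of 9, 1 and 3 alone; 0.0427 and 0.16) and cholesterol synthesis (1 and 5 of 15, 1 and 5 alone; 0.0427 and 0.554, and 0.0663 with the size factors of DESeq2) were also lower. Primed genes (6 and 0 of 12, 8 and 0 alone; 0.000252 and 0.0143), fibroblast genes (5 and 0 of 9, 8 and 0 alone; 2.89e-11 and 0.000105), mesoderm (3 and 0 of 9, 3 and 0 alone; 0.00764 and 0.0852), DNA methylation (4 and 0 of 8, 5 and 0 alone; 0.00764 and 0.16) and glycolysis (4 and 1 of 16, 4 and 1 alone; 0.0427 and 0.0852) were higher. The count was 2233 and 1992 without hatched replicate 1 and 3, 2056, 1975 and 2095 without epiblast replicate 1, 2 and 3, 1426 against a fold threshold of 2 and 5231 in a fit of the 2 groups alone.

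The embryo counterpart of the naive and primed states was examined as epiblast against the mean of the 5 blastocyst ICM stages (n = 3 and 15 libraries). NLRP7 fell from 1990 ± 1100 CPM in the ICM to 35.4 ± 5.61 CPM in the epiblast, DPPA5 from 347 ± 113 to 9.12 ± 1.7 CPM and ESRRB from 31.8 ± 18.3 to 0.25 ± 0.315 CPM. DNMT3B rose from 170 ± 121 to 4100 ± 51.1 CPM, ZIC2 from 11.8 ± 13 to 215 ± 10.4 CPM and SFRP2 from 25.4 ± 73.9 to 1370 ± 64.3 CPM. BECN2, at 15.1 ± 7.93 CPM in the ICM, had no count in the epiblast and was at least 831-fold lower. SERPINA1, a protease inhibitor of liver and yolk sac, rose from 0.0508 ± 0.139 to 2690 ± 121 CPM. DCN (ENSCJAG00000019513), a matrix proteoglycan of fibroblasts, rose from no count to 500 ± 25 CPM, at least 128000-fold.

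edgeR called 7579 of 16929 genes (44.8%), 4418 higher and 3161 lower in the epiblast. With the size factors of DESeq2, median log2 values were 0.24 higher here and 0.20 higher from hatched ICM to epiblast than with TMM, and no called gene changed sign. NLRP7 fell by 5.68 ± 0.36 (adjusted p = 2.4e-08) and DPPA5 by 5.24 ± 0.42 (2.41e-07), while DNMT3B rose by 4.68 ± 0.31 (3.19e-08), and for each the 3 epiblast libraries lay outside the range of the 15 ICM libraries. Other large rises were PAMR1, a muscle and matrix protease-like gene (no count to 352 ± 16.6 CPM, at least 90100-fold), and COL3A1, a fibrillar collagen, 179000-fold higher with a counting interval of 32200 to 7090000 from 1 count in the ICM. Among the largest falls were ABCB4, a phospholipid transporter (213 ± 170 CPM to no count, at least 12200-fold lower), and ALPP, an alkaline phosphatase (70.3 ± 74.3 CPM to no count, at least 3800-fold lower). The folds of PAMR1, ABCB4 and ALPP are lower bounds, that of COL3A1 is a ratio, and none of them has a rank. Against a fold threshold of 2, 4751 genes were called.

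8 of 27 lists were called between epiblast and ICM, and 6 of these with an estimated correlation. The naive list had 1 higher and 11 lower of 14 (1 and 12 adjusted over the list alone; median -4.54; camera adjusted p = 4.7e-07, and 0.0243 with an estimated correlation). The gene that rose was IL6ST, the shared receptor of LIF and IL6, from 17.1 ± 10.9 to 128 ± 5.4 CPM. The primed list had 11 higher and 0 lower of 12 (11 and 0 adjusted over the list alone; median 5.21; camera adjusted p = 1.19e-06, and 0.00327 with an estimated correlation). Oxidative phosphorylation genes were lower, with 0 higher and 24 lower of 25 (0 and 24 adjusted over the list alone; median -2.09; camera adjusted p = 8e-15, and 0.0243 with an estimated correlation), and SDHB fell from 336 ± 66.8 to 29.3 ± 10.4 CPM. Fibroblast genes had 9 higher and 0 lower of 9 (9 and 0 adjusted over the list alone; median 12.28; camera adjusted p = 2.77e-09, and 0.000497 with an estimated correlation). Mesenchymal genes had 7 higher and 0 lower of 8 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00246, and 0.0243 with an estimated correlation) and glycolysis 9 higher and 1 lower of 16 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0161, and 0.0407 with an estimated correlation). The mesoderm list had 7 higher and 0 lower of 9 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00234, and 0.0751 with an estimated correlation), with KDR rising from 0.882 ± 1.48 to 537 ± 27.7 CPM. The DNA methylation list had 7 higher and 0 lower of 8 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00433, and 0.136 with an estimated correlation), with TET1 rising from 54.5 ± 34.3 to 293 ± 45.3 CPM. The primitive endoderm list had 7 higher and 2 lower of 16 (8 and 3 adjusted over the list alone; adjusted p = 0.239), including APOB, an apolipoprotein, which rose from 0.629 ± 1.89 to 482 ± 28.1 CPM, and GATA6, which fell from 1000 ± 910 to 83.6 ± 15.2 CPM.

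Gene by gene, the naive minus primed log2 change was then set against the ICM minus epiblast log2 change of the embryo, over 16136 genes tested in both, from comparisons that share no library. Across genes, which are not independent replicates, Pearson's r was 0.634 for DSY-c2 (Spearman's rho 0.58) and 0.57 for N40 (rho 0.5). Of the genes called in both, 4645 of 5183 (89.6%) went the same way in DSY-c2 and 4199 of 5026 (83.5%) in N40. BECN2, ESRRB, DPPA5 and NLRP7 were higher in both naive cells and ICM, and ZIC2, SFRP2, SALL2, DNMT3B and KDR were lower in both. In every epiblast library 9 of 9 tested fibroblast and 16 of 16 primitive endoderm genes stood at 10 CPM or more. The epiblast side may thus include other cell types, and these correlations were not recomputed without their markers. The 2 conversions correlated at r = 0.749 (rho 0.755) over 17957 genes, and 8055 of 8257 genes called in both (97.6%) went the same way. With hatched ICM in place of the 5 ICM stages, r was 0.536 and 0.492.

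**Figure D3:**
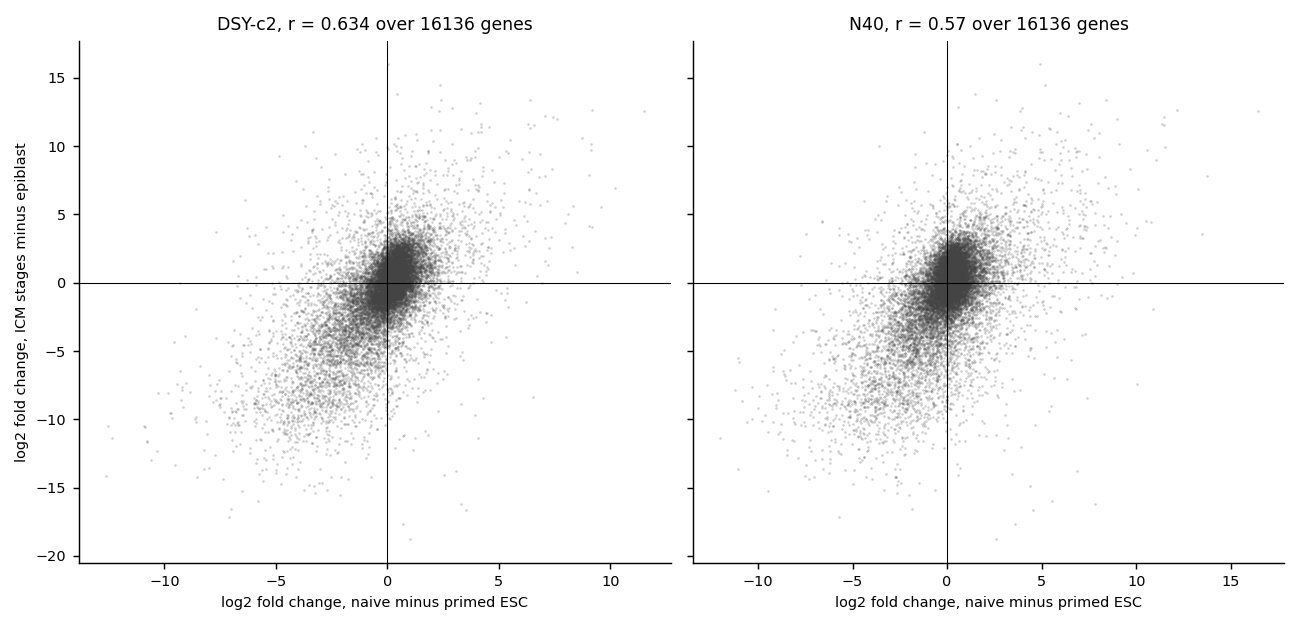
Log2 fold change of ICM minus epiblast (vertical axis) against naive minus primed cells (horizontal axis) for DSY-c2 and N40, each point 1 of 16136 genes. Pearson's r across genes was 0.634 in DSY-c2 and 0.57 in N40.

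Each ESC library was also correlated with the embryo stages over the 6435 genes that differed among stages. Naive libraries had a mean r of 0.886 (DSY-c2) and 0.884 (N40) with the mean of the ICM stages, and 0.681 and 0.665 with the epiblast. For primed libraries the r with the epiblast was 0.825 (DSY127), 0.816 (No.40), 0.806 (DSY-c2) and 0.78 (N40), and the r with the ICM 0.705, 0.698, 0.721 and 0.709. Of the 7 stages the epiblast was the nearest to each of the 12 primed libraries, the hatched ICM to the 3 DSY-c2 naive libraries and the hatching ICM to the 3 N40 naive libraries. The margins in the naive libraries were small. With hatching and hatched ICM, r was 0.882 and 0.892 in DSY-c2 naive replicate 2, and 0.879 and 0.881 in replicate 3. In N40 naive replicates 1 and 3 it was 0.882 and 0.882, and 0.878 and 0.873. Whether the 2 lines match different blastocyst stages was not tested. The difference of the 2 correlations (ICM minus epiblast) was 0.205 ± 0.013 in DSY-c2 naive against -0.086 ± 0.0086 in primed libraries, and 0.219 ± 0.003 against -0.071 ± 0.0044 in N40 (SD, n = 3). The naive minus primed difference was 0.291 in DSY-c2 and 0.29 in N40, each with a two-sided exact permutation p of 0.1, the smallest that 20 arrangements can give. With labels exchanged within line over both lines, it was 0.29 with an exact permutation p of 0.005, the smallest that 400 arrangements can give. With all expressed genes in place of the 6435, this difference was 0.142.

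**Figure D4:**
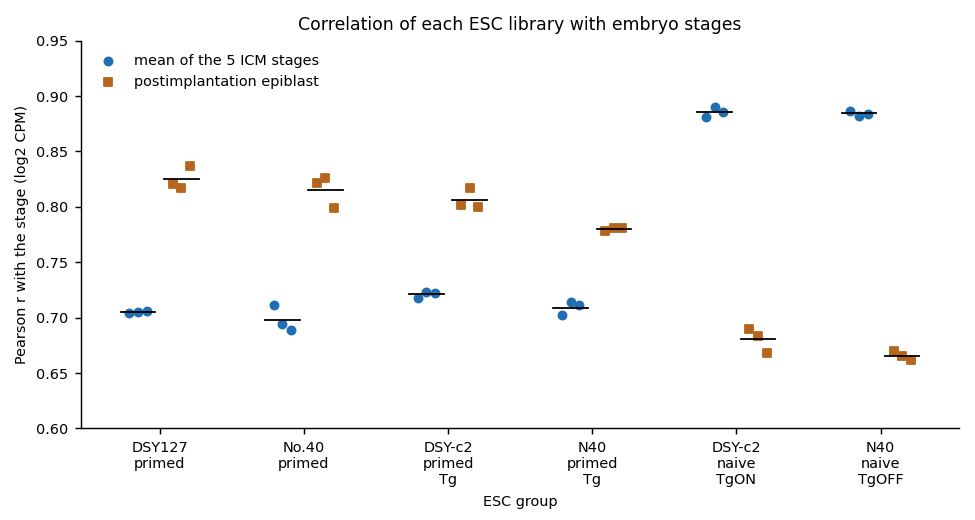
Pearson's r of each ESC library with the mean of the 5 blastocyst ICM stages and with the postimplantation epiblast, over 6435 genes; each point is 1 of 18 libraries, by group. Naive groups averaged 0.886 and 0.884 with the ICM, and the 4 primed groups averaged 0.78 to 0.825 with the epiblast.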

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

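The tests of starting level, level reached and column suffix, and the counts of other splits of the libraries, were chosen only after the result was seen. The naive effect differed between DSY-c2 and N40 for 2716 genes in a test of the difference itself, which is what singled these results out. TgON and TgOFF go with the cell line here, so a difference between lines and one between these titles cannot be told apart.

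Log2 differences of the effects (DSY-c2 minus N40) among named genes were -6.03 for KLF17, -3.14 for DPPA5, -2.35 for NLRP7, -1.79 for KLF4, -2.47 for KLF5, -0.95 for NANOG, -1.24 for TFAP2C and 0.69 for IL6ST in the naive list. They were 3.59 for CYTL1, -0.83 for DNMT3B, -2.24 for FGF2 and -2.93 for NEFL in the primed list, and -1 for LIN28B, 0.81 for MYC and -0.69 for SALL4 in the shared and reprogramming lists. Further differences were -11.35 for GATA6, -11.33 for POSTN, -9.92 for TLX1, -9.49 for ARGFX, 6.8 for JPH1, 6.47 for NPPB and 5.83 for FOSB. ARGFX and TLX1 had no count in N40 primed libraries and JPH1 none in N40 naive libraries, so these 3 fitted values are no bound and have no rank. The call for DNMT3B ended without any library of these 4 groups except DSY-c2 primed replicate 4 and N40 primed replicate 1 (adjusted p = 0.062 to 0.146). That for FGF2 ended without DSY-c2 primed replicate 4, DSY-c2 naive replicate 2 or 3, N40 primed replicate 1 or 2, or N40 naive replicate 1 or 2 (0.0535 to 0.0974). That for TFAP2C ended without DSY-c2 primed replicate 2 or 5, DSY-c2 naive replicate 1 or 2, N40 primed replicate 3, or N40 naive replicate 2 or 3 (0.0507 to 0.0825). That for IL6ST ended without DSY-c2 primed replicate 4, DSY-c2 naive replicate 2, N40 primed replicate 1, or N40 naive replicate 1 or 3 (0.0566 to 0.0806). In a fit of these groups alone the adjusted p was 0.0511 for DNMT3B and 0.0657 for TFAP2C, and with the suffix as a covariate 0.0548 for IL6ST. The list difference was negative for naive genes (camera adjusted p = 0.00033), WNT response (0.0174) and zygotic genome activation (0.00212). It was positive for oxidative phosphorylation (0.000505) and epithelial genes (0.00879). With an estimated correlation the adjusted p was, in that order, 0.366, 0.428, 0.333, 0.428 and 0.428, so none of these 5 lists was called. The sign is that of DSY-c2 minus N40 and not the size of an effect. Median log2 changes were -2.43 in DSY-c2 and 0 in N40 for WNT genes, and 0.04 and -0.22 for epithelial genes.

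Of 40 splits of the libraries between the lines within a state, the real one included, 3 gave at least the 2716 genes of the real split, which is 1 of these 3. The other 2, with 3607 (the highest) and 2859 genes, moved 6 primed libraries together and 2 naive libraries, 1 of each line. They kept the primed difference between the lines whole, but with its sign turned, since all primed libraries swapped their line. For that difference 6314 genes were called, and 6127 for the one between the naive groups. Such splits still hold a difference between the lines, so their counts do not measure chance alone. Other splits of the same make-up gave 2048 and 1325 genes. Whether the primed difference accounts for the larger counts was not tested, and chance was not excluded by this count.

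The smaller effects of naive genes in DSY-c2 had a median difference of -2.41 over 8 called members. Over these members DSY-c2 primed libraries stood 1.95 above N40 primed libraries on the log2 scale (median), and 6 of 8 were called higher. DSY-c2 naive libraries stood at -0.4 against N40 naive libraries (median), with 2 of 8 called lower: KLF4 at -1.66 and NANOG at -1.26, which were not called between the primed groups (0.13 and -0.32). With the column suffix as a covariate, 8 of 8 stayed called. The difference of effects is the naive minus the primed difference by construction, so these values describe where it lies and test no explanation. The 6 members called higher between the primed groups were not called between the naive groups (edgeR adjusted p = 0.169 to 0.879). KLF4 and NANOG were called between the naive groups only. The difference thus lay in the starting level for some members and in the level reached for others, though a missing call does not show equal levels. Why these levels differed stays open, and line, culture and Tg were not separated.

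For the counts of called genes, the splits of 3 against 3 libraries were too few for a share under 0.05. The real count and the highest of the other splits were 10565 and 0 (DSY-c2; 1 of 10 splits as large), 10952 and 0 (N40; 1), 337 and 0 (Tg against DSY127; 1), 3937 and 15 (Tg against No.40; 1), 802 and 3 (DSY127 against No.40; 1), 1042 and 4 (morula to early; 1) and 3372 and 0 (hatched to epiblast; 1). They were 5 and 75 from early blastocyst to blastocyst (2 as large), and 0 and 5, 0 and 0, and 0 and 2 in the next 3 steps (10 as large in each), where edgeR found 923, 831 and 1134 genes at an unadjusted p under 0.05 and DESeq2 called 356, 278 and 245. The real split alone of 40 gave as many genes for the mean naive effect (12514 against 5950) and epiblast against ICM (7579 against 2020). The same held for the F test (6435 against 204). That share of 0.025 is the smallest that 40 splits can give. The splits were chosen after the results were seen, so they do not exclude chance.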

How the results depend on the processing

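Halved counts, the column suffix, similarity with a library or markers left out, and concordance over genes of at least 1 CPM in a primed group were chosen only after the data were seen, and the other alternatives before. Counts of called genes stayed within 1.5 times their value with the size factors of DESeq2, without a low-count filter, with the stricter filter and with halved counts. The share of calls that were higher shifted with the size factors of DESeq2. It went from 52.3% to 48.4% for the mean naive effect and from 36.2% to 45.6% from hatched to epiblast. The similarity difference between naive and primed cells kept its sign under each alternative run, at 0.142 with all expressed genes to 0.303 with a prior count of 0.5. Among named genes, no setting turned the direction of a gene called in the main fit or under that setting. Sign changes of genes called in neither were not counted. Unless the setting itself shows it (fewer libraries or a fold threshold), the cause was not tested.

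Against a fold threshold of 2, calls numbered 3761 (DSY-c2), 4266 (N40), 315 (their difference), 4636 (their mean), 179 (Tg against DSY127), 494 (Tg against No.40), 44 (DSY127 against No.40), 265 (morula to early), 3 (early to blastocyst), 1426 (hatched to epiblast) and 4751 (epiblast against ICM). DESeq2 called 547 (Tg against DSY127), 1532 (DSY127 against No.40), 2946 (morula to early), 1201 (early to blastocyst) and 356, 278 and 245 in the next 3 steps, where edgeR called 0 (923, 831 and 1134 at an unadjusted p under 0.05). Fits of only the groups compared called 1748 (Tg against No.40), 430 (DSY127 against No.40), 213 (morula to early), 0 (early to blastocyst, where edgeR on all embryo libraries called 5 and found 2255 at an unadjusted p under 0.05, and DESeq2 called 1201) and 5231 (hatched to epiblast). With the suffix as a covariate, 100 genes were called for Tg against DSY127.

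With 1 library left out, calls ranged over 146 to 262 for Tg against DSY127 (149 without DSY127 replicate 1; 146, 186 and 149 without DSY-c2 primed replicate 2, 4 and 5), 2571 to 4740 for Tg against No.40 (2571 without N40 primed replicate 2) and 368 to 1165 for DSY127 against No.40 (403, 377 and 399 without DSY127 replicate 1, 2 and 3; 368 and 470 without No.40 replicate 2 and 3; 1165 without No.40 replicate 1). They ranged over 513 to 949 from morula to early (513 and 581 without morula replicate 1 and 2), 4 to 127 from early to blastocyst (127, 14 and 12 without early replicate 1, 2 and 3; 103 and 10 without blastocyst replicate 1 and 2), 0 to 1 from blastocyst to expanded (1 without blastocyst replicate 1, with 923 at an unadjusted p under 0.05 and 356 by DESeq2 on all libraries) and 1975 to 2884 from hatched to epiblast (2233 and 1992 without hatched replicate 1 and 3; 2056, 1975 and 2095 without epiblast replicate 1, 2 and 3).

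Concordance with the embryo was 0.625 in DSY-c2 and 0.523 in N40 over genes above the median level, 0.536 and 0.492 against hatched ICM only, and 0.676 and 0.595 over genes of at least 1 CPM in a primed group. It ranged over 0.611 to 0.63 and 0.544 to 0.57 with 1 library left out. Between the lines it was 0.839 above the median level and 0.722 to 0.755 with 1 library left out. Of 378 pairs of list and comparison, 72 were called with the preset correlation, 13 with an estimated correlation and 122 with fry. By comparison, camera and fry called 4 and 19 of 27 lists (DSY-c2), 6 and 14 (N40), 5 and 10 (their difference), 4 and 18 (their mean), 5 and 0 (Tg against DSY127), 8 and 9 (Tg against No.40) and 7 and 8 (DSY127 against No.40). In the embryo they called 4 and 8, 4 and 3, 0 and 0, 3 and 0, 5 and 0, and 9 and 13 at the 6 steps in order, and 8 and 20 for epiblast against ICM.

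No pairing by replicate number was seen, since in no comparison did all same-numbered libraries deviate together at r over 0.1. With 3 libraries per group this cannot show that they were unpaired, and the labels do not say. With a block, 20 of 78 called named genes lost their call from hatched to epiblast and 13 of 40 from morula to early. A block for the number gave 12 calls from early to blastocyst and 1 from hatching to hatched, and counts within 1.5 times in the other comparisons with shared numbers. No paired analysis was possible for comparisons with DSY-c2 primed libraries because they share fewer than 2 numbers with the other group.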

Other observations

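All tests in this part were chosen only after the result was seen. In the postimplantation epiblast libraries, 9 of 9 tested fibroblast genes stood at 10 CPM or more in every library, against 1 of 9 in every ICM library, with medians of 234 and 0.0239 CPM and COL3A1 at 234 ± 18.8, DCN at 500 ± 25 and POSTN at 227 ± 20.6 CPM. The same held for 16 of 16 primitive endoderm, 4 of 9 mesoderm, 5 of 11 trophectoderm, 1 of 4 maternal tissue and 1 of 5 amnion genes, against 7, 0, 1, 1 and 0 in the ICM. In primed ESCs 5 of 11 fibroblast genes stood at that level in every library and 11 in at least 1 library. Their mean log2 CPM was 5.37 to 7.11 in DSY127 and No.40 libraries and 2.47 to 4.63 in Tg primed libraries, and whether fibroblast or feeder cells were present in those cultures was not tested. Library size was close, at a ratio of 1.01. Cells of other types in the collected tissue are a candidate explanation, and a change within the epiblast itself was not tested.

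In DSY-c2, 7 mesoderm genes were lower in naive than in primed cells (median -6.36), and primed replicate 4 held the highest CER1 level. Without that library 6 of 7 stayed called (median -4.2), EOMES not (-2.72, adjusted p = 0.113). With the column suffix as a covariate 6 of 7 stayed called (median -5.63), EOMES not (-4.09, adjusted p = 0.0723). Without that library the median was smaller in size, so part of it rested on that library, while 6 of 7 calls stayed. The suffix varied within only the No.40 and DSY-c2 naive groups of ESCs, so the covariate rested on few libraries. DSY-c2 naive replicates 1 and 2 carry the suffix of the 3 primed libraries. Their mean mesoderm levels were -1.2 and -1.22 (log2 CPM), against 2.23 to 4.48 in primed libraries. These 7 genes were picked by their calls in the same data, and a mixture of states in primed cultures remains untested.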
